A study of Mus musculus with 2 samples.

How the data were processed

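The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of EP300 in the liver of newborn mice. EP300 (also called p300) is a histone acetyltransferase that transcription factors recruit to active enhancers and promoters. The labels give 1 group of 2 replicates, mouse strain B6NCrl, tissue liver, age 0 days, with sex given as not collected. Both replicates carry the same biosample and donor labels, so by these labels the spread between them is that of libraries and immunoprecipitations. Whether they come from 1 animal or from a pool is not given in the sources used here.

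Peak lists on mouse genome build mm10 were used, 5 in all: 1 list per replicate, 1 list called on both replicates together (the pooled list), and 2 lists thresholded by the irreproducible discovery rate (IDR), named optimal and conservative. Per the file headers and descriptions deposited with the lists, each was made from aligned reads with a control alignment, and the IDR lists were made from both replicates' lists and the pooled list. The aligner, the peak caller, the IDR threshold and all versions are not given in the sources used here. In every list the authors' signal value is a score per peak from the peak caller, and its scale is not stated. It was used to rank, describe and compare peaks within a list, and between the replicates only for correlations and a median log2 ratio. For 1 test of chromosome X it was divided by a set factor, which the unstated scale does not warrant. In the deposited replicate lists, column 9 is the −log10 q-value of each peak. In the pooled and IDR lists the deposited values of that column fall below 0 for some peaks, which no q-value can give, so there it was treated as a score. The IDR lists also hold an authors' IDR score, up to 1000. In both IDR lists the signal value is that of the pooled list, which adds nothing independent to the replicates. No list gives read counts, so the depth of each sample is unknown, and every interval covers the counting of peaks or genes only. The md5 sums of all 5 peak files were those listed in the deposited descriptions. The series files held 0 columns of samples from other series.

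Gene positions came from GENCODE mouse release M21 (GRCm38, the same assembly as mm10), and sequences came from the GRCm38 genome. On 21 of 21 chromosomes every peak of every list ended inside the reference chromosome. Peaks on chromosomes 1 to 19, X and Y were analysed. Peaks on the mitochondrial genome and on unplaced contigs were counted and left out. Coordinates are 1-based. Each peak was placed by its summit, first as promoter (within 1 kb of a protein-coding transcription start site, TSS), then as exon, intron or intergenic. How reads that align to several near-identical places were treated is not given in the sources used here, so values at repeated genes, such as the globin genes and the histone genes, are uncertain.

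The comparison the design implies is that of both replicates with each other and with the IDR lists. The highest peaks of each replicate by signal value, as many as the optimal list holds, were called shared when they overlapped by at least 1 base, with a 95% Clopper-Pearson interval and 100 seeded shuffles within chromosomes as the background. Correlations were computed across matched peaks. The other results describe the optimal list, made by the authors from both replicates. Promoter and distal signal were compared by a two-sided permutation test with 100000 resamples and a bootstrap interval of 2000 resamples. For 28 gene lists, a gene counted as having a peak when a summit lay within 10 kb of one of its TSSs. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 28 lists, at a threshold of 0.05. Of 569 listed symbols, 4 had no protein-coding match and were left out. Genes of a cluster share peaks, so genes are not independent. For 34 motifs, the window of 50 bases on each side of the summit was compared with a window centred 500 bases away on a random side by a two-sided exact McNemar test, with Benjamini-Hochberg adjustment over the motifs. A p-value written as below 1e-300 had reached the smallest value stored. Motifs were fixed consensus sequences, searched on both strands, and a match does not show which protein bound. Motif shares were also compared by Fisher's exact test between the strongest and weakest 20% of peaks, and between peaks near hepatocyte genes and peaks near erythroid genes, within 50 kb of a TSS. For that comparison, hepatocyte genes were those of the secreted protein, transcription factor, urea cycle and coagulation lists only. Peaks were stitched into clusters when their summits lay within 12 kb. The p-values of gene and motif tests describe 1 peak list. They do not measure variation between animals.

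The gene lists, motifs, tests and alternatives were fixed before the data were examined, and so was the rule for naming genes. That rule names the nearest gene within 50 kb of the 15 strongest peaks, the 3 members of each list with the strongest peak within 10 kb, and up to 2 members without a peak in each list past the threshold. It also names the nearest genes of the 8 clusters with most peaks, and a fixed set of genes in every case, among them Alb, Afp, Ttr, Apoa1, Hnf4a, Foxa2, Cebpa, Gata1, Klf1, Tal1, Hba-a1, Hbb-bs, Ep300, Cyp7a1, Pck1 and Igf2. The text names a subset of these. Results were also computed with the conservative list, the top 50% of the optimal list by signal, each replicate's own highest peaks in place of the IDR list, and other distances, windows, control sequences, overlap rules and backgrounds. The background alternatives included 10000 random gene lists matched on the number of TSSs within 50 kb. The share of motifs in each 10% of peaks by signal, and the tests named as such in the closing part, were added afterwards.

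The peak overlap, the gene list test, the paired motif test, the difference of medians and the stitching of clusters were tested on simulated data. The other computations were not, among them the correlations, the location shares, the matched random lists and the Fisher's exact tests of motifs. All 13 quantities were recovered within the tolerance set, 14 of 14 planted lists of 20 genes were called, 0 of 14 random lists were called, and 0 motifs were called on 8000 random windows. Nearly every gene of the planted lists was given a peak, so smaller excesses were not tried. The random windows were drawn as random bases, so they do not test the motif calls on genome sequence. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.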

Results

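EP300 binding was profiled by ChIP-seq in the liver of newborn mice, an organ in which hepatocytes stand beside the blood-forming cells of the fetal liver. One group of 2 replicates was collected. Each replicate's own list held 300000 peaks, and so did the list called on both replicates together. The optimal IDR list held 26883 peaks, of which 26844 lay on chromosomes 1 to 19 and X and were analysed, and the conservative list held 23700. Read depth is unknown, since the lists give no read counts. All signal values below are the authors' unscaled values, compared within a list and, between the replicates, only as correlations and a median ratio, and all coordinates are on mm10.

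The strongest EP300 peaks lay at the same places in both replicates. The strongest peak of the optimal list lay between genes on chromosome 5 (96919237 to 96919618), 77.4 kb from the nearest TSS, that of Anxa3, a gene outside the naming rule that was chosen after its values were seen. It ranked 1 in replicate 1 and 2 in replicate 2. The peak in an intron of Nprl3, the gene whose introns hold the known enhancers of the alpha-globin genes, ranked 13 and 1. Among the highest peaks of replicate 1, 18561 of 26860 (69.1%, 95% Clopper-Pearson interval 68.5 to 69.7) overlapped one of the highest of replicate 2. Seen from replicate 2 the share was 68.9%, against a mean of 0.822% and a highest value of 0.953% in 100 shuffles. Of replicate 1's 5000 strongest peaks, 99.9% overlapped some peak of replicate 2, and of those ranked 200001 to 300000, 16.5% did. The background is higher against that full list, with a mean of 8.50% in 20 shuffles for all peaks of both replicates. Across 17919 matched peaks, which are not independent replicates, signal values gave Spearman's rho 0.785 and Pearson's r 0.884 on the log2 scale, with rho between 0.731 and 0.831 within single chromosomes. Replicate 1's signal values were higher by a median log2 ratio of 0.90 (SD 0.47 across peaks), a difference of scale that the lists do not explain. In the alternatives the overlap left the interval of 68.5 to 69.7%, except when peaks were ranked by q-value (69.1%). That ranking ordered ties by signal and gave 18559 shared peaks, almost the same as the ranking by signal, so it tests little. The overlap ranged from 83.6% for the top 5000 to 29.3% for all 300000 peaks of each list.

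**Figure D1:**
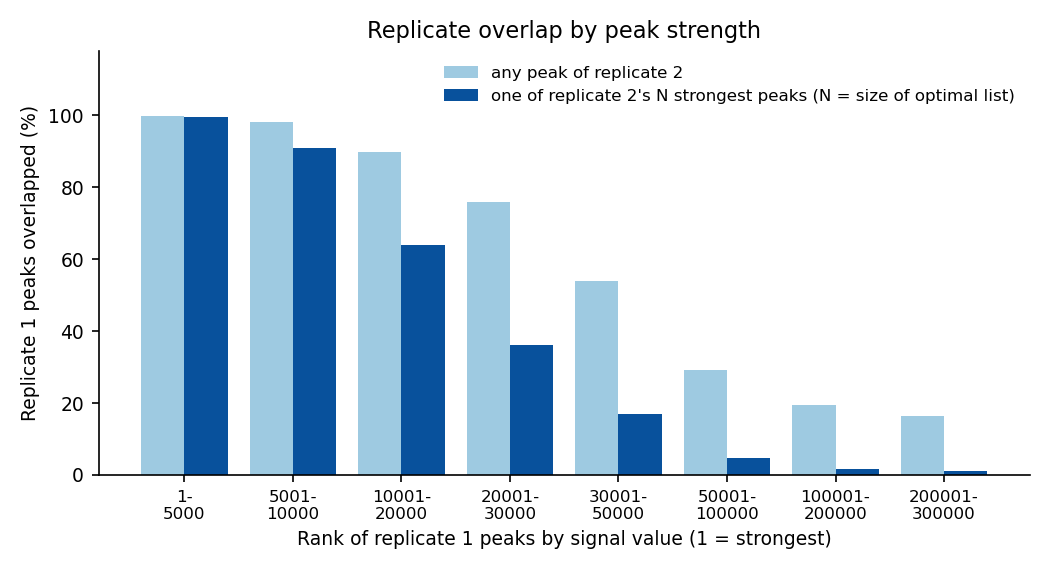
Replicate overlap by peak strength. The horizontal axis groups the peaks of replicate 1 by rank of signal value, and the vertical axis gives the percentage that overlapped any peak of replicate 2 (light bars) or one of its highest peaks, as many as the optimal list holds (dark bars); the light bars fall from 99.9% to 16.5%.

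The optimal and conservative lists held largely the same peaks, but neither contained the other. Of the conservative peaks, 19980 (84.3%) were also optimal peaks. The other 3720 were not, although 719 of them overlapped an optimal peak. Peaks in both lists had a median signal of 47.4, against 23.4 for the 6903 peaks of the optimal list alone and 22.9 for those of the conservative list alone. Nearly all optimal peaks overlapped a peak of replicate 1 (99.8%) and of replicate 2 (95.9%), the lists from which the optimal list was made. Fewer overlapped one of the highest peaks of replicate 1 (85.9%) and of replicate 2 (76.4%).

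Red cell genes stood beside some of the strongest peaks of the liver. An intronic peak of Gypc, which encodes glycophorin C (chromosome 18, 32542335 to 32542791), had a signal of 590. Other peaks among the 15 strongest lay near Hipk1, a protein kinase gene (585), 29.8 kb from Cd24a, a surface glycoprotein of immature blood cells (582), in an intron of Smtnl1 (568) and 1.09 kb from Ap5s1 (562). Of the 15, 6 lay over 50 kb from every protein-coding TSS, so that the nearest gene says little about their target.

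Both globin loci carried runs of strong peaks away from the globin genes themselves. At the alpha-globin locus on chromosome 11, 7 summits lay within Nprl3 (32225628 to 32267707), with signals of 603 (summit 32251088), 556 (32245816), 303 (32256324) and 285 (32265306) at the strongest. The peak of 556 has Mpg, a DNA repair gene that overlaps the end of Nprl3, as its nearest TSS. The alpha-globin gene Hba-a1 (32283511 to 32284465) had 4 summits within 10 kb, of which the nearest, 1.81 kb away, was at 43.6. At the beta-globin locus on chromosome 7, the strongest summits between the embryonic gene Hbb-y and the olfactory receptor gene Olfr66 had signals of 363, 433, 426, 478 and 570. This stretch is known as the locus control region. The adult gene Hbb-bs (103826534 to 103828096) had a promoter peak of 204, with 126 and 79.6 in the replicates. The stretch from 103854861 to 103877310 had the highest summed signal of all peak clusters, 2576, over 9 peaks.

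**Figure D2:**
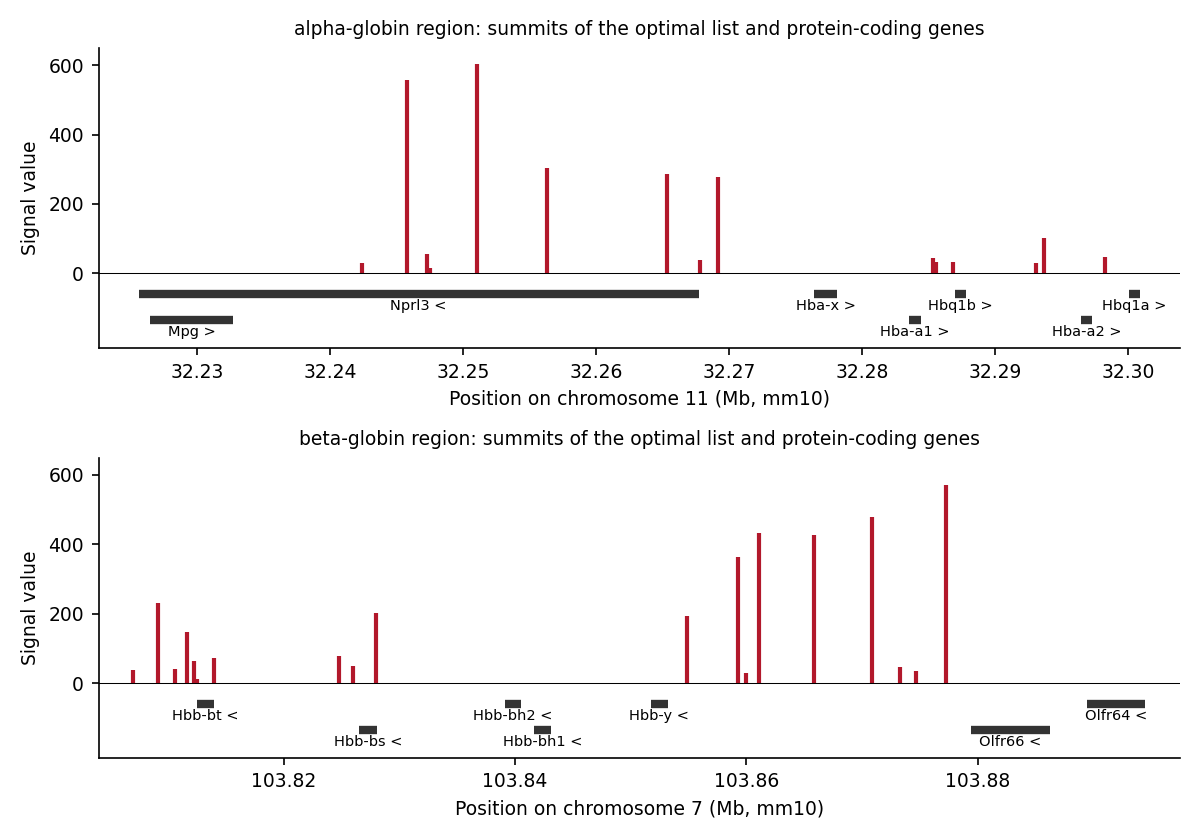
EP300 peaks at the alpha-globin locus (top) and the beta-globin locus (bottom). Each vertical bar stands at the summit of an optimal peak (horizontal axis, position in Mb on mm10) with its signal value as height; dark boxes are protein-coding genes with an arrowhead for the strand. The highest bars, 603 and 570, stand in Nprl3 and next to Olfr66.

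Peaks were frequent at promoters, but most lay elsewhere. Promoters held 5607 of the 26844 summits (20.9%, interval 20.4 to 21.4), 7.89 times the mean of 2.65% in shuffled lists. The promoter of Pcx, which encodes pyruvate carboxylase, held one of the stronger ones (chromosome 19, summit 4558756, signal 264), and the promoter of the albumin gene Alb a moderate one (chromosome 5, summit 90460884, signal 49.9). Introns held 40.5% against 37.2% in shuffles, intergenic sequence 36.2% against 57.6%, and exons 2.37% against 2.56%. The median distance from a summit to the nearest TSS was 11.7 kb. The share at promoters depends on the distance chosen and reached 35.8% within 5 kb.

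Promoter peaks were slightly weaker than distal peaks. The median signal was 36.8 at 5607 promoter peaks and 38.7 at 21237 distal peaks, a log2 difference of -0.07 (bootstrap interval -0.11 to -0.04, permutation p = 5e-05). With replicate 2's own highest peaks, without replicate 1, the difference was -0.01 (p = 0.51, permutation test) and was no longer past the threshold. It was -0.18 within the top 50% of peaks and -0.04 with promoters taken as 5 kb.

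Genes of proteins that hepatocytes secrete were nearly all marked. Of the 21829 protein-coding genes, 8324 (38.1%) had a summit within 10 kb of a TSS. Among genes of hepatocyte secreted proteins 25 of 26 did (odds ratio 40.7, Fisher's exact test with Benjamini-Hochberg adjusted p = 7.7e-09). Alb (chromosome 5, 90460897 to 90476602) had its one peak within 10 kb at 0.013 kb upstream of a TSS, and Afp, which encodes the fetal counterpart of albumin, had one 2.25 kb upstream at 54.8. The strongest peaks of the list lay 9.64 kb upstream of Ahsg, which encodes fetuin-A (173), near Cp, which encodes ceruloplasmin (121), and at the promoter of the fibrinogen gene Fga (109). Promoter peaks stood at Ttr, which encodes transthyretin (52.5), and at the apolipoprotein gene Apoa1 (49.3). Serpina6 was the member without one. With 23 and 24 members marked, the odds ratio was 12.7 without replicate 1 and 17.4 without replicate 2, and it was lowest, 9.27, with distal peaks only.

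Among metabolic genes of the liver, the urea cycle, glucose and lipid lists lay above other genes. Of the urea cycle and amino acid catabolism genes, 23 of 24 had a peak (adjusted exact p = 3.3e-08), with 171 in an intron of Fah, the last enzyme of tyrosine breakdown, 163 near Ass1 of the urea cycle, and 145 at the promoter of Cth. Otc, a urea cycle gene on chromosome X, had none within 10 kb, its nearest peak lying 12.6 kb away. Of the genes of glucose metabolism, 15 of 16 had a peak (adjusted exact p = 2.5e-05), among them Pcx and Pck1, which encodes the rate-limiting enzyme of gluconeogenesis (promoter, chromosome 2, summit 173152791, 108), while Irs2 had none. Lipid metabolism genes had 23 of 30 (adjusted exact p = 0.00012), led by an intronic peak of the fatty acid transporter gene Cd36 (402), Angptl4 (173) and Cpt1a, which encodes the gatekeeper of mitochondrial fatty acid oxidation (162). Fasn and Scd1, which encode enzymes of fatty acid synthesis, had none. Acute phase genes had 15 of 19 (adjusted exact p = 0.0016), among them Il1r1 (351) and the metallothionein genes Mt1 and Mt2, which share a peak of 230, while Saa1 and Saa2 had none.

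Among hepatocyte transcription factors 15 of 22 genes had a peak (odds ratio 3.48, adjusted p = 0.0172, Fisher's exact test with Benjamini-Hochberg adjustment). The strongest stood at the promoter of Hhex (141), in an intron of Rxra (128) and downstream of Nr0b2 (61.5 and 38.2 in the replicates). Hnf4a (chromosome 2, 163506808 to 163572910) had an intronic peak of 99.0 and Cebpa one 2.65 kb upstream at 47.9. Foxa1 and Foxa2 had no peak within 10 kb, the nearest to Foxa1 lying 98.8 kb away. The call was lost with the top 50% of peaks (adjusted exact p = 0.0975), within 1 kb (0.203) and within 50 kb of a TSS (0.165), while the odds ratio was 5.97 with distal peaks only.

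The 4 other liver lists did not pass the test within 10 kb, though each did under at least 1 alternative. Genes of bile acid synthesis and transport had 10 of 16 (adjusted exact p = 0.1), with an intronic peak of 357 at the phospholipid exporter gene Abcb4, 114 upstream of the bile acid importer gene Slc10a1, and 41.2 at the promoter of Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis. Xenobiotic metabolism genes had 11 of 20 (adjusted exact p = 0.209), with 300 near Ugt1a1 and 189 in an intron of Por. The coagulation and complement list had 13 of 27 (adjusted exact p = 0.361), with its strongest peak of 85.3 at the C3 promoter. The list of the IGF axis and growth hormone signalling had 8 of 14 (adjusted exact p = 0.209), with 139 upstream of Igfbp1 and 31.7 at an Igf2 promoter. The bile acid list passed in 7 of 9 alternatives, among them without replicate 1 (adjusted exact p = 0.00136) and without replicate 2 (0.0162). Xenobiotic metabolism passed in 5 of 9, these among them (exact, 0.000765 and 0.0192), coagulation without replicate 2 (0.0455) and within 50 kb (0.00313), and the IGF list with nearest TSSs only (0.0107).

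Nearly all erythroid genes had a peak, and the strongest peak of each gene tended to be high. Of 37 genes, 35 had a summit within 10 kb (odds ratio 28.5, adjusted p = 1.6e-11, Fisher's exact test with Benjamini-Hochberg adjustment). Their strongest peaks had a median signal of 232, against 60.2 for the hepatocyte secreted proteins, 93.8 for the urea cycle and amino acid list and 49.5 for all genes with a peak. Over all peaks within 50 kb of a listed TSS, the medians were closer, at 48.9 for 270 erythroid-gene peaks and 41.3 for 426 peaks of the secreted protein, transcription factor, urea cycle and coagulation genes (log2 difference 0.24, bootstrap interval 0.05 to 0.62). Peaks of 1 gene are not independent, so that interval may be too narrow. Strong erythroid-gene peaks stood 7.18 kb upstream of the carbonic anhydrase gene Car2 (519, with 299 and 212 in the replicates) and 4.30 kb upstream of Rhag, which encodes a red cell ammonium channel (509). The genes of the erythroid master factors carried peaks as well, with 220 in an intron of Gata1 (chromosome X, 7959260 to 7978071), 182 at the Klf1 promoter (chromosome 8, 84901928 to 84905291) and 158 at the Tal1 promoter (chromosome 4, 115056426 to 115071755). Bcl11a, the repressor of fetal globin, and Slc25a37, a mitochondrial iron importer gene, had none. The erythroid odds ratio was 59.6 without replicate 1, 25.4 without replicate 2 and 10.6 with distal peaks only. Megakaryocyte and platelet genes had 15 of 20 (adjusted exact p = 0.0027), with 314 in an intron of Mmrn1, 160 in Tubb1 and 148 in Plek, and lost the call within 1 kb (adjusted exact p = 0.265).

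Other blood lists did not exceed the background within 10 kb. Blood stem and progenitor cell genes had 9 of 18 (adjusted exact p = 0.361), although Lyl1 (325) and Lmo2 (300) had strong promoter peaks and Runx1 an intronic one (150). The granulocyte list had 10 of 18 (adjusted exact p = 0.197), with 209 downstream of Cebpe, and the macrophage and Kupffer cell list 5 of 18 (adjusted exact p = 0.487), with 166 upstream of Hmox1 and 157 at the promoter of the iron exporter gene Slc40a1. Lymphoid genes had 2 of 17, below the background (odds ratio 0.216, adjusted exact p = 0.0433), with Lck and Cd3d the members with a peak and Cd79a among those without. The lymphoid call was lost in 5 alternatives, among them without replicate 2 and with the conservative list (adjusted exact p = 0.477 and 0.094), and within 50 kb the list lay 23.9 percentage points above other genes (adjusted exact p = 0.0702). The granulocyte list passed without replicate 2 (adjusted exact p = 0.0162), with the conservative list (0.0376) and within 50 kb (0.0491). With nearest TSSs only, within 50 kb, 15 of the 18 stem and progenitor cell genes had a peak (adjusted exact p = 0.00112).

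Marker genes of the minor liver cell types gave no call within 10 kb. Endothelial cell genes had 12 of 19 (adjusted exact p = 0.053), with 103 near Egfl7 and 61.3 upstream of Stab2. Stellate and mesenchymal cell genes had 4 of 18 (adjusted exact p = 0.263), yet Reln had a peak of 505 located 3.92 kb upstream. Bile duct cell genes had 3 of 16 (adjusted exact p = 0.18), which were Aqp1 (248), Notch2 (168) and Sox4 (107). The endothelial list passed without replicate 1 (adjusted exact p = 0.0435), with the conservative list (0.0255), with nearest TSSs only (0.0288) and with distal peaks only (0.046), and the stellate list lay below other genes within 1 kb (0 of 18, 0.0423).

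Among lists that no single cell type owns, immediate early genes had 16 of 17 (adjusted exact p = 1.2e-05), with 336 near Btg2, 197 near Junb and 168 in an intron of Dusp1, and none at Klf4. Circadian clock genes had 14 of 18 (adjusted exact p = 0.0027), with 217 in an intron of Per1, 116 at the Arntl promoter and 99.8 near Nr1d1, but none at Clock. Cytosolic ribosomal protein genes had 23 of 27 (adjusted exact p = 4.6e-06), with 346 in an intron of Rpl3 and 297 at the Rpl32 promoter. Housekeeping genes had 13 of 20 (adjusted exact p = 0.0386), with 177 near Snrpd3. With only distal peaks, ribosomal genes lay at -4.19 percentage points from other genes (adjusted exact p = 0.881). The housekeeping call was lost without replicate 2 (adjusted exact p = 0.153), against matched random lists (permutation, 0.103), with distal peaks only (0.478) and with the top 50% of peaks (0.186).

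Genes of other tissues had few peaks. Muscle genes had 2 of 20 (adjusted exact p = 0.0207), neuron genes 3 of 21 (adjusted exact p = 0.0433) and pancreas genes 1 of 16 (adjusted exact p = 0.0188), all below the background. Myod1, Myog, Syn1, Snap25 and Cpa1 had none, and the pancreas member with a peak was Cela1 (224). The epidermis list had 2 of 15 (adjusted exact p = 0.095), and lung and kidney 5 of 16 (adjusted exact p = 0.798), with 165 in an intron of Slc12a3. The epidermis list passed, below other genes, without replicate 1 (adjusted exact p = 0.0242), with the top 50% of peaks (0.0438) and within 50 kb (0.0119). The neuron call was lost against matched random lists (adjusted permutation p = 0.0922), with the top 50% of peaks (exact, 0.186) and with distal peaks only (0.274), and those of muscle and pancreas in 5 alternatives each, among them distal peaks only (exact 0.103 and 0.21). In total, 12 of the 28 lists lay above other genes and 4 below. Against matched random lists 11 lay above and 3 below.

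**Figure D3:**
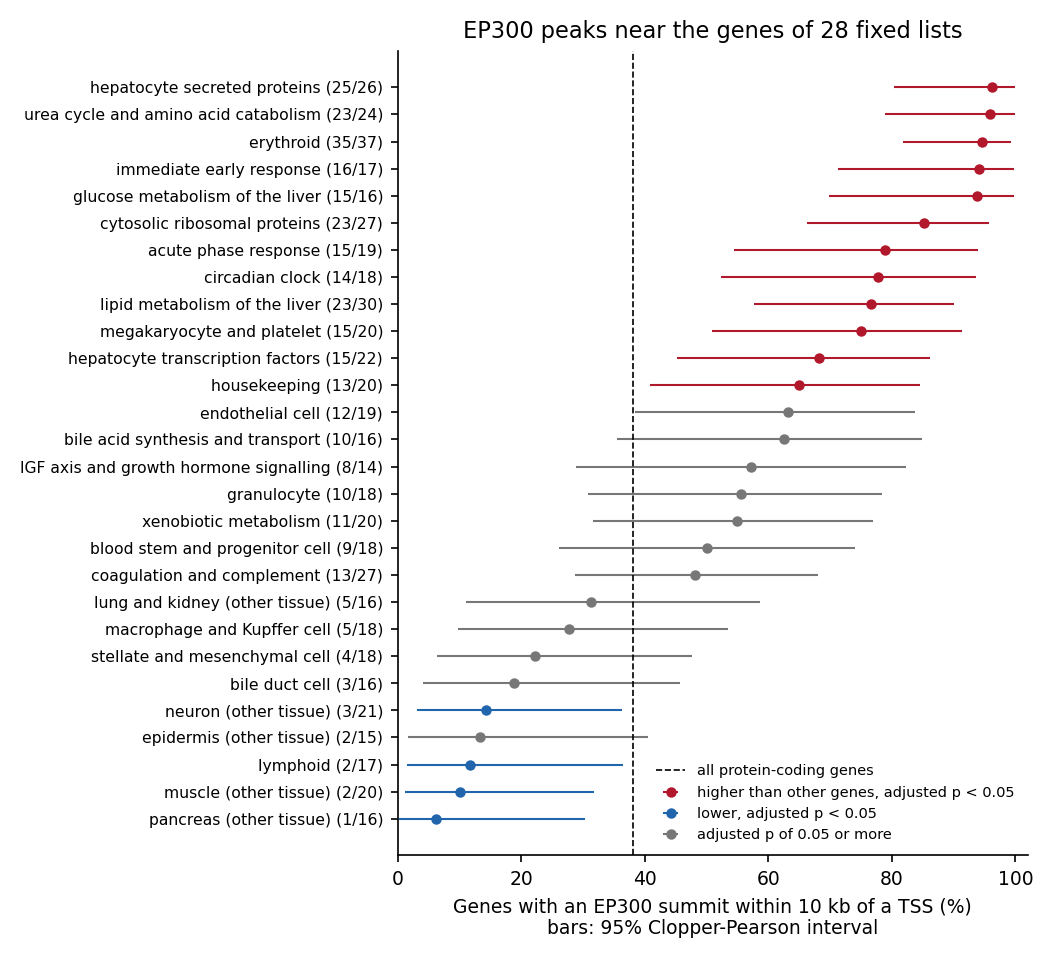
Share of genes with an EP300 summit within 10 kb of a TSS for the 28 gene lists. Points give the percentage of members with 95% Clopper-Pearson bars, numbers in brackets are members with a peak over all members, and the dashed line is the 38.1% of all protein-coding genes; red lists lay above other genes and blue lists below at an adjusted p under 0.05. The hepatocyte secreted, urea cycle and erythroid lists stand at the top.

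EP300 itself had 1 peak within 10 kb of a TSS of its gene Ep300 (chromosome 15, 81585351 to 81652077), 7.57 kb upstream, with signals of 71.5 and 29.5 in the replicates.

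Sequences of blood and liver transcription factors lay under the summits. The GATA sequence, bound by GATA1 in red cell precursors and by GATA4 in hepatocytes, stood within 50 bases of 8816 of 26844 summits (32.8%), against 9.36% of control windows (ratio 3.51, interval 3.37 to 3.65, exact McNemar p below 1e-300). The GATA and E-box composite, bound by the GATA1 and TAL1 complex, stood at 9.34% against 0.566% of control windows (ratio 16.5). Among other sequences of blood factors, the ratio was 6.55 for NFE2, 2.32 for RUNX, 2.56 for PU.1, 1.67 for KLF and 1.32 for the E-box of TAL1 type. Among those of liver factors it was 4.4 for the HNF4A repeat, 3.95 for CEBP, 2.98 for NFI, 1.95 for ONECUT, 1.58 for FOXA and 2.36 for HNF1. Nuclear receptor repeats gave 2.21 for the degenerate direct repeat, 1.85 for PPAR/RXR, 1.89 for FXR and 1.23 for LXR/TR. General factors gave 5.7 for CREB/ATF, 3.41 for ETS, 2.88 for STAT, 2.65 for AP-1, 2.12 for SP1, 2.44 for YY1, 1.85 for NFY, 1.66 for the E-box of USF type and 1.6 for CTCF. MYOD (1.74), MEF2 (1.81) and RFX (1.5), taken as sequences of other tissues, were higher too.

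In total 29 of 34 sequences were higher at summits after Benjamini-Hochberg adjustment. TEAD was lower (ratio 0.915, adjusted p = 0.0226, exact McNemar test). NR5A2, REST, OCT4-SOX2 and TP63 did not pass. At promoter peaks alone 17 sequences were higher, and LXR/TR was lower there (ratio 0.583, adjusted exact p = 0.0234). HNF1 had 5.33 without replicate 1 and 4.0 without replicate 2, and lost the call with the conservative list (1.86, adjusted exact p = 0.102) and the top 50% of peaks. LXR/TR lost it with both lists too (adjusted exact p = 0.192 and 0.222), and CTCF with the top 50% (0.17). NFE2 had 4.11 without replicate 1, and the composite 25.5 with the top 50% and 9.83 with a window of 100 bases. NFY did not pass at distal peaks (1.11, adjusted exact p = 0.286) and had 4.5 at promoters, while CREB/ATF had 3.18 and 20. YY1 lost the call with the conservative list (adjusted exact p = 0.106), the top 50% (0.078), distal peaks (0.644) and promoter peaks (0.0888). RFX lost it in 6 alternatives, among them without replicate 1 (adjusted exact p = 0.38), and MEF2 in 4, among them without replicate 2 (0.0552). At promoter peaks HNF1, the HNF4A repeat, the degenerate repeat, FOXA, RUNX, NFE2, MYOD and the E-box of TAL1 type also did not pass. TEAD did not pass with control windows 1000 bases away, with a window of 100 bases, or at distal or promoter peaks alone.

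**Figure D4:**
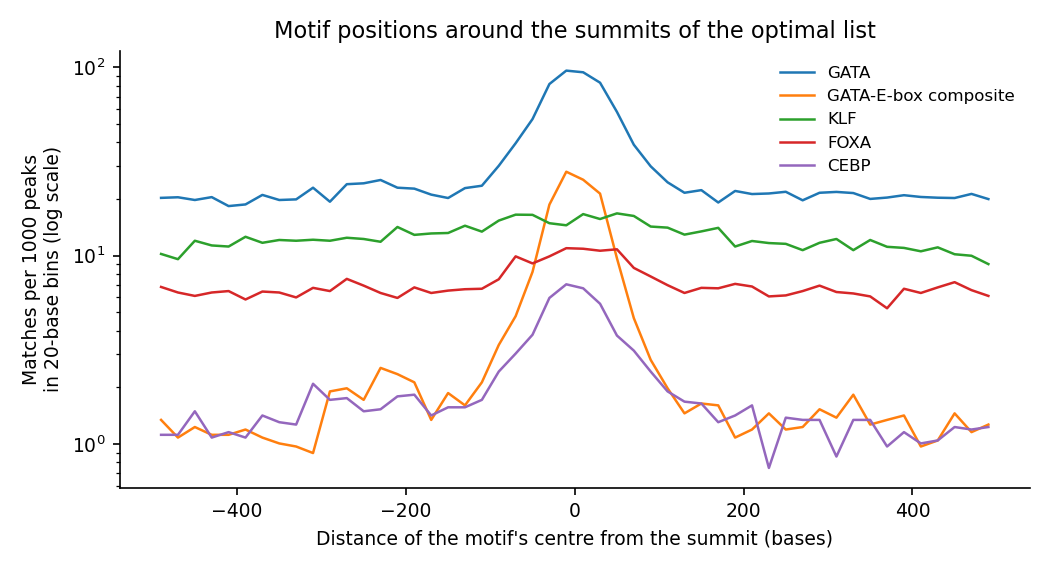
Positions of 5 motifs around the summits of the optimal list. The horizontal axis is the distance of the motif's centre from the summit in bases, and the vertical axis (log scale) the number of matches per 1000 peaks in bins of 20 bases; GATA, its composite with an E-box and CEBP rise within about 100 bases of the summit, while KLF and FOXA rise less.

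The summits of named genes show such sequences. The 61 bases around the strongest Nprl3 summit (chromosome 11, 32251058 to 32251118, intron) read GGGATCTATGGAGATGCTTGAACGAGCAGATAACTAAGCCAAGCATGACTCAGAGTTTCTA and match GATA and AP-1. Those at the Klf1 promoter (chromosome 8, 84901289 to 84901349) read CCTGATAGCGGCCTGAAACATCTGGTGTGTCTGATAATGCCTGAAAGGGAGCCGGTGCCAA and match GATA, the composite and the E-box of TAL1 type. Those in the Gata1 intron (chromosome X, 7971448 to 7971508) read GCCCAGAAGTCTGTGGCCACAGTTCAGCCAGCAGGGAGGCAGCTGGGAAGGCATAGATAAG and match GATA and the composite. At the Cth promoter (chromosome 3, 157925024 to 157925084) the sequence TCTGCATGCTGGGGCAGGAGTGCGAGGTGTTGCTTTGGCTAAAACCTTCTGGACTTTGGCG matches the HNF4A repeat. These 4 were chosen from the named genes after their values were seen.

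The strongest peaks were the richest in GATA sequences. Among the strongest 20% of peaks (5368), 59.2% had a GATA sequence, against 18.2% of the weakest 20% (odds ratio 6.51, interval 5.95 to 7.12, Fisher's exact p below 1e-300). For the composite the shares were 22.7% and 3.13% (odds ratio 9.11, interval 7.71 to 10.8). The E-box of TAL1 type (odds ratio 1.62), NFE2 (2.83), RUNX (1.54), STAT (1.57) and MYOD (1.74) were higher in strong peaks as well. ETS (0.574), PU.1 (0.552), NR5A2 (0.623), TEAD (0.745) and CTCF (0.432) were higher in weak peaks, all with Benjamini-Hochberg adjusted p-values of 0.0258 or less. The HNF4A repeat, HNF1, FOXA, CEBP and ONECUT did not pass in favour of strong peaks. A comparison of both ends misses a maximum in between. CEBP stood at 1.27% of the strongest 10% of peaks, 3.65% of the fifth 10% and 1.30% of the weakest 10%. The HNF4A repeat, at 0.26%, 1.04% and 0.41%, and ETS, at 1.34%, 5.21% and 2.20%, had the same shape. FOXA and ONECUT were also lowest in the strongest 10%. From the strongest to the weakest 10% of peaks, GATA fell from 70.5% (68.8 to 72.2) to 14.8% (13.5 to 16.2). RUNX and STAT lost the call without replicate 2 and with the conservative list, as did TEAD, and NR5A2 lost it there and without replicate 1. Without replicate 2, 8 sequences in place of 5 were higher in weak peaks.

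**Figure D5:**
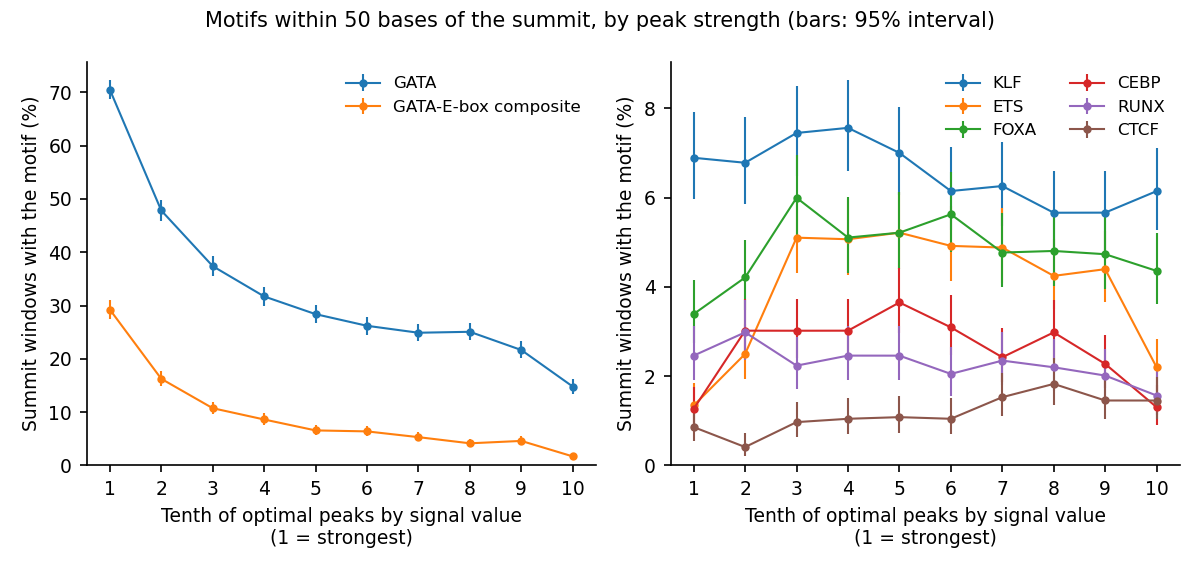
Share of summits with a motif within 50 bases, by signal. The optimal list is divided into 10 equal parts by signal value (1 is the strongest, horizontal axis), and points give the percentage of summits with the motif with 95% Clopper-Pearson bars; GATA falls from 70.5% to 14.8% and its composite with an E-box from 29.2% to 1.68% (left), while KLF, ETS, FOXA, CEBP, RUNX and CTCF stay under 10% (right).

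Peaks near hepatocyte genes and peaks near erythroid genes differed in sequence. The tests count each peak once, but the peaks stood near no more than 99 hepatocyte and 38 erythroid listed genes. Peaks of 1 gene are not independent, so the p-values may be too small and the intervals too narrow. Within 100 bases of the summit, CEBP stood at 5.87% of 426 peaks near genes of the secreted protein, transcription factor, urea cycle and coagulation lists and 0.741% of 270 erythroid-gene peaks (odds ratio 8.34, interval 2.05 to 73.2, Fisher's exact test with Benjamini-Hochberg adjusted p = 0.00438). The PPAR/RXR repeat stood at 8.22% and 2.22% (odds ratio 3.93, adjusted exact p = 0.00676). GATA was the reverse, at 27.2% and 50.7% (odds ratio 0.364, adjusted exact p = 2.1e-08), and so was the composite, at 6.1% and 21.1% (odds ratio 0.243, adjusted exact p = 1.1e-07). FOXA, at 13.8% and 7.41%, did not pass (adjusted exact p = 0.0665), but did with the conservative list (0.0441), without replicate 1 (0.0216) and without replicate 2 (0.0114), and ONECUT passed without replicate 1 (0.0258). With fewer peaks, within 10 kb of a TSS or distal alone, CEBP kept odds ratios of 10.4 and 6.10 but not the call (adjusted exact p = 0.0629 and 0.0547). It was 3.88 without replicate 1, 4.09 with the conservative list and 14.3 with the top 50% of peaks. PPAR/RXR had 2.74 and 3.21 with those fewer peaks (0.347 and 0.0834, exact), 2.29 without replicate 1 (0.11), 4.71 without replicate 2 (0.0109) and 18.7 with the top 50% (0.000275). GATA and the composite had 0.215 and 0.121 within 10 kb, and GATA 0.205 with the top 50%. NFE2 (without replicate 1, 0.044, exact) and the E-box of TAL1 type (without replicate 2, 0.0114) were lower at hepatocyte-gene peaks.

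Chromosomes differed in peak density. Chromosome 19 held 17.6 peaks per Mb, chromosome 11, with the alpha-globin locus, 16.6, and chromosome 14, the lowest autosome, 7.21. Per protein-coding gene they held 1.43, 1.21 and 0.976 peaks, against 1.28 for all autosomes. Chromosome X, which carries Gata1 and Otc, held 413 peaks, or 2.53 per Mb (0.229 of the density of the autosomes), with 2.45 and 2.52 among the highest peaks of the replicates, and chromosome Y none. Over all peaks of the replicates, the density of chromosome X was 0.538 and 0.577 of that of the autosomes.

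Peaks gathered in clusters. With summits within 12 kb stitched together, 43.4% of peaks (interval 42.8 to 44.0) lay in 2716 clusters of at least 3 peaks, against 4.54% in shuffles. Overlapping peaks counted as separate members, while the shuffles placed each peak independently of the others and of promoters. The cluster with most peaks, 28, lay over histone genes around Hist1h4f (chromosome 13, 23517729 to 23609332). Next came 24 peaks near Picalm, a gene of clathrin-mediated endocytosis (chromosome 7, 90019752 to 90080569), 19 around Btg2, an antiproliferative gene, and 17 across Bcl2l1, which encodes the survival factor of red cell precursors BCL-XL (chromosome 2, 152784780 to 152831640). Sgms1 had 17, and 16 each lay near Gtf3c5, near Glrx5, which acts in iron-sulfur cluster assembly, and near Tubd1. The Gtf3c5 cluster also holds peaks nearest to Gfi1b, which encodes an erythroid and megakaryocyte repressor and was chosen after its values were seen. The share in clusters was 23.9% with a stitching distance of 5 kb.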

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

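Of the tests weighed here, those of the promoter share and of the cell share with 1 value per gene, the gene density of chromosome X and the overlap of weak peaks with stronger ones were chosen after the result was seen.

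The optimal list held 25 peaks on the mitochondrial genome, covering 9564 bases with signals from 8.99 to 67.5, and 14 on unplaced contigs with signals up to 84.7, all outside the chromosomes analysed. Nothing in the series tests where these came from.

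The strongest peak of erythroid genes was stronger than that of hepatocyte genes (secreted protein, transcription factor, urea cycle and coagulation lists), while over all peaks within 50 kb the log2 difference was only 0.24 (0.05 to 0.62). With 1 value per gene, the strongest peak, it was 1.95 (bootstrap interval 1.69 to 2.31, 35 against 76 genes). The permutation p was 0.0001, the smallest 10000 permutations can give. Each gene counts once there, so a few genes with many strong peaks cannot make it, but this value restates the flagged pattern. The strongest of several peaks also tends to be higher where a gene has more of them. Within 10 kb, 135 erythroid-gene peaks stood beside 35 genes and 194 hepatocyte-gene peaks beside 76. Over all peaks with the replicates apart the smaller difference was 0.34 (0.14 to 0.64), so neither replicate alone carried the difference over all peaks. The strongest-peak difference was not computed per replicate, and the peaks had passed a threshold on agreement between both replicates. Intervals over all peaks count the peaks of 1 gene as independent, so they may be too narrow. For the difference over all peaks, a different share of promoters was left open by distal peaks within 50 kb, at 0.20 (-0.04 to 0.62). The strongest-peak difference remained without promoter peaks, at 2.11 (1.14 to 2.51) for the strongest distal peak of each gene. That value again takes the strongest of several peaks, and it says nothing of the difference over all peaks. If more erythroid cells alone scaled all their peaks by 1 factor, distal peaks and promoters should differ equally, provided that the same peaks stayed listed. The distal difference minus the promoter difference was -1.58 (-2.13 to -0.29). Without distal peaks nearest to other genes it was -1.36 (-2.05 to -0.05), an interval that nearly reached 0. These medians cover only peaks past the threshold of the list, and a scaling would also change which peaks pass it. They therefore cannot decide the question. With 1 value per gene the distal difference minus the promoter difference was 0.26 (-0.59 to 1.18) and decides nothing either. The cell mixture was not measured and stays open as an explanation.

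Chromosome X held few peaks. Per protein-coding gene its density was 0.342 (0.309 to 0.376) of that of the autosomes, so its lower gene density does not account for the difference. A single copy of chromosome X per cell, if it divided signal values by 2, was computed to give 0.411 of the autosomal density per gene at a fixed signal limit, above the 0.331 (interval up to 0.366) found, and if by 3, a setting chosen after that result, 0.234. The bound set before the result took a division by 2, but the scale of the score is not given in the sources used here, so a single copy stays open, and sex is given as not collected. Chromosome Y held 0 peaks of replicate 1's full list and 1 of replicate 2's. That speaks against males with a single chromosome X only if chromosome Y was not filtered, which is not given in the sources used here. Over all peaks of the replicates, chromosome X had 0.538 and 0.577 of the autosomal density per Mb, so the shortage was smaller there, and no explanation besides gene density and copy number was tested.

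Some optimal peaks were weak in the pooled list: 675 (2.51%) ranked beyond 100000, of which 141 had the highest IDR score of 1000. Of the 675, 93.5% (91.3 to 95.2) overlapped a stronger pooled peak, against 4.94% of other peaks of those ranks, and 87.6% (84.8 to 90.1) of those shared a replicate peak with it in both replicates. Both results are consistent with weak calls that took the score of a stronger neighbour, at a median summit distance of 208 bases. How the lists were matched is not given in the sources used here.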

How the results depend on the processing

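No alternative was chosen after the data were seen, except in tests named as such above, and the cause of changes listed here was not tested unless the alternative's construction gives it. Read depth is unknown, so how far it limits the weaker peaks cannot be said.

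The share of replicate 1's highest peaks found in replicate 2 was 62.3% with reciprocal overlap of 50%, 60.6% with summits within 100 bases, 83.6% for the top 5000, 56.2% for the top 50000 and 29.3% for all peaks. Spearman's rho was 0.726 for the optimal list and 0.892 for the top 5000. The share of peaks at promoters was 19.97% in the conservative list, 19.8% in the top 50%, 17.5% within 500 bases, 35.8% within 5 kb, 27.0% with TSSs of all genes, and 18.03% and 22.8% without replicates 1 and 2. Promoter minus distal signal was -0.0111 and -0.0699 (log2) without replicates 1 and 2. Peaks in clusters were 23.9% at 5 kb and 61.8% at 25 kb, since the distance sets what is joined, and 38.5% and 41.0% without replicates 1 and 2.

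Hepatocyte transcription factors stood 20.3 percentage points above other genes with the top 50%, 14.1 within 1 kb and 17.4 within 50 kb, none of them a call any longer. Lymphoid genes reversed to 23.9 within 50 kb, and cytosolic ribosomal proteins to -4.19 with distal peaks only. Of 252 alternative values for 28 gene lists, 197 kept their call, 26 lost it, 27 gained it and 2 reversed.

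At promoter peaks 17 motifs were higher at summits, with fewer peaks. With control windows 1000 bases away, a window of 100 bases, or distal peaks only, 0 were lower. Ratios reversed for HNF1 (0.9, top 50%) and, at promoter peaks, for LXR/TR (0.583), the E-box of TAL1 type (0.868) and MYOD (0.985). Of 303 values 270 kept their call, 29 lost it, 0 gained one and 4 reversed. Between hepatocyte-gene and erythroid-gene peaks, 0 motifs were higher at 10 kb or with distal peaks only, both with fewer peaks, and 158 of 169 values kept their call. Between strong and weak peaks, 6 and 8 motifs were lower without replicates 1 and 2, and 107 of 131 values kept their call.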

Other observations

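The comparisons of motifs between promoter and distal peaks, and of the highest peaks with gene lists, were chosen after the results were seen. The test of motif spacing was written before its result.

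Promoter peaks and distal peaks carried different sequences. SP1 stood at 6.69% of promoter peaks and 0.824% of distal peaks (odds ratio 8.63, interval 7.17 to 10.4), NFY at 5.30% and 1.24% (4.46), CREB/ATF at 1.07% and 0.254% (4.24), KLF at 12.4% and 5.00% (2.70) and ETS at 7.12% and 3.16% (2.35). GATA was the reverse, at 12.8% and 38.1% (0.237, interval 0.218 to 0.258), and so was its composite with an E-box, at 3.51% and 10.9% (0.298). Among the 100 strongest peaks, 82 had a GATA sequence, 15 lay within 50 kb of a TSS of an erythroid gene, and 0 of the 99 genes of the secreted protein, transcription factor, urea cycle and coagulation lists. Among the 1000 strongest the counts were 784, 54 and 1. The other liver lists, which hold Cd36 (402), Abcb4 (357), Il1r1 (351) and Pcx (264), were not counted here.

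The GATA1 and TAL1 complex is known to bind a GATA sequence and an E-box at a fixed distance. Of the spacings of 0 to 20 bases between a CTG and a GATA sequence, 8 bases was the most frequent at summits, with 1338 summits, 4.28 times the mean of the other spacings. In control windows the ratio was 0.893. The spacings of 7 and 9 bases followed, with 708 and 510 summits.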
